A study of Danio rerio with 28 samples.

How the data were processed

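Gene expression was measured by RNA sequencing in 28 libraries, each made from a pool of 10 to 15 guts dissected from zebrafish larvae at 7 days post-fertilization. RNA was prepared with a Norgen single-cell kit and libraries with a TruSeq stranded mRNA kit, and paired reads of 100 bases were sequenced on a NovaSeq 6000, per the labels' protocols. FastQC 0.11.8 and the zebrafish genome build danRer11 are named in the submitters' processing notes; the aligner, the counting tool, its strand setting and the gene annotation are not given in the sources used here. The libraries fell into 2 experiments. Experiment 1 held wild type and il22 knockout guts whose housing the labels do not state, and experiment 2 held wild type and knockout guts under conventional or germ-free (axenic) rearing together with knockout larvae that were co-housed. Each of the 7 groups had 4 libraries. Because each library is a separate pool of animals, p-values measure the spread between these pools, not between single larvae.

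For each experiment the authors deposited a table of raw read counts per gene and a table of TPM (transcripts per 1e+06), a unit normalized by the authors for gene length and library total. The deposited count table of experiment 1 had 16134 rows named by transcript identifiers, of which 15776 were given a gene symbol through the RefSeq annotation of assembly GCF_049306965.1 (GRCz12tu), used for names and neighbouring genes only. The 358 rows with no symbol held 0.414% of the counts and were kept under their identifiers. Among these rows, 1407 shared 622 symbols, and 98.57% of the counts of such symbols lay in their largest row, which is the row named here. The table of experiment 2 had 15419 rows named by symbols: 14311 were current, 909 were updated through a unique older symbol, and 199 kept the name in the table. In total 14926 names were found in both tables. TPM was missing for 1886 rows of experiment 1, which held 1.4% of the counts. The 2 experiments were counted separately, so levels were tested only within a table, and effects of the knockout were compared between tables. Levels of il22 and of genes that separated the genotypes in every library were also set side by side across the tables, as a description without a test.

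Changes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, robust dispersion, quasi-likelihood F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. Experiment 1 was fitted alone, and the 5 groups of experiment 2 were fitted together so that they share 1 estimate of the spread. The difference between the knockout effects of the 2 experiments was fitted on the 16 libraries of experiment 1 and of the conventional groups of experiment 2. All adjusted p-values of single genes come from this test unless stated otherwise. CPM values are counts per 1e+06 counts of the TMM-scaled library, log2 fold changes are given with an approximate standard error (SE), and the first-named group is the numerator. This SE is the absolute log2 fold change divided by the square root of the F statistic. It is uncertain where a group has few or no counts. Fixed gene lists of pathways and cell types, 30 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. No list called at the preset correlation was called with the estimated correlation. A library's score for a list is the mean log2 CPM of its genes. The knocked-out gene was compared with exact permutation tests, two-sided, because in experiment 2 it fell under the count filter.

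The genes to name, the lists, the designs and most alternatives were fixed before the data were examined. After il22, the named genes are the 10 of largest rise and the 10 of largest fall in 4 comparisons, and 5 of each in the others, among genes past the threshold with no overlap between the groups, a mean of at least 5 CPM in the higher group and a symbol that is not a clone name, followed by up to 4 genes of smallest p in each list. For the interaction and for the difference between experiments, non-overlap was not required. Not every gene this rule takes is printed. Members of a list may also be named where its count is given. Where every library of a group had no count, the fold is a lower bound against 3 counts over the whole group, which covers counting error only. Genes with close copies (the ggact, plxnb2a, cela1, crp, krt, ifi27 and haemoglobin families, among others) are uncertain, since the counting could have split their reads.

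Library totals, in units of 1e+06 counts, were 30.24 to 37.95 in experiment 1 and 22.26 to 31.0 in experiment 2. The test was run on simulated counts with 200 genes changed and a further list of genes shifted by a smaller fold. For the knockout in experiment 1, over 10615 genes, 32.8% of the genes changed 1.5-fold, 74.2% of those changed 2-fold and 96.9% of those changed 4-fold were recovered, and 5.6% of calls were unchanged genes. For the conventional comparison of genotypes, over 11162 genes, the shares recovered were 40.3%, 76.9% and 98.5%, with 2.6% of calls unchanged. For co-housing, over 11175 genes, they were 45.5%, 76.9% and 89.4%, with 2.7% of calls unchanged. For the difference between experiments, over 10940 genes, they were 9%, 55.2% and 87.9%, with 7.3% of calls unchanged. In these simulations edgeR's test missed changes of 1.5-fold more often than it found them, while DESeq2 recovered 55.2% in the conventional comparison. The DESeq2 share ignored the direction of change and came without a share of unchanged genes among its calls. Far more genes were called between the genotypes in the data than were changed here. The Benjamini-Hochberg threshold depends on the share of changed genes, so these recoveries are no estimate of sensitivity in the genotype comparisons of the data.

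Alternatives were DESeq2 1.42.0, its size factors in edgeR, no count filter, limma on log2 of the TPM plus 1 or plus 0.1, the compared groups fitted alone, a covariate for pancreas and liver transcripts, removal of the tissue lists, the replicate number as a block, and each library left out in turn. Added after seeing the data were the summing of rows that share a symbol, removal of 3 libraries with muscle transcripts, thinning of the libraries to the smallest total, and a split of the libraries shared by the co-housing and germ-free comparisons. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.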

Results

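The study profiled the gut transcriptome of zebrafish larvae with and without il22, the gene of interleukin-22, a cytokine that acts on epithelial cells through STAT3, and asked by its title how that cytokine, gut motility and the microbiota are connected. Counts were analysed for 28 libraries in 7 groups of 4. Totals, in units of 1e+06 counts, averaged 34.78 ± 2.62 (SD, n = 4) in wild type and 32.24 ± 1.38 in the knockout of experiment 1. In experiment 2 they averaged 29.14 ± 2.07 in conventional wild type, 26.82 ± 3.03 in germ-free wild type, 25.84 ± 0.84 in the conventional knockout, 24.91 ± 1.56 in the germ-free knockout and 23.72 ± 1.76 in the co-housed knockout. The 10 most abundant genes took 14.33% to 19.59% of the counts of a library. Skeletal muscle genes averaged 5.40, 4.57 and 3.72 on the log2 CPM scale in conventional wild type 1, germ-free wild type 2 and co-housed knockout 2, against at most 2.2 in the other libraries. Liver genes averaged 2.65 to 3.82 in the conventional wild type libraries and ranged from −0.305 to 3.78 in the other libraries of experiment 2.

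il22 was measured first, because it checks the labels. In experiment 1 it stood at 7.50 ± 4.35 CPM in wild type (SD, n = 4; 164 to 464 counts per library) and at 0.906 ± 0.784 CPM in the knockout (5 to 58 counts), a log2 fold change of −3.05 ± 0.67 with an adjusted p of 0.0101. Every knockout library lay below every wild type library, which gave an exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow, and 0.2 after adjustment over the 7 comparisons of il22. In experiment 2 il22 was near the limit of detection. It averaged 0.360 ± 0.325 CPM in conventional wild type (1 to 18 counts) and 0.177 ± 0.119 CPM in the conventional knockout (1 to 9 counts), with an exact permutation p of 0.4. Germ-free guts had 0.0668 ± 0.0890 CPM in wild type (0 to 5 counts) and 0.0298 ± 0.0198 CPM in the knockout (0 to 1 count), with an exact permutation p of 0.714. The co-housed knockout had 0.330 ± 0.470 CPM, with 1.03 CPM in library 4. At these levels il22 neither supported nor opposed the labels of experiment 2. The lowest wild type level of experiment 1, 3.99 CPM, would have given 88.8 counts in the smallest library of experiment 2, so depth alone did not set the low counts there. il26, the neighbouring cytokine gene of the same family, stood at 0.943 ± 0.780 CPM in wild type and 0.171 ± 0.198 CPM in the knockout of experiment 1 (n = 4; adjusted p = 0.0525).

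**Figure D1:**
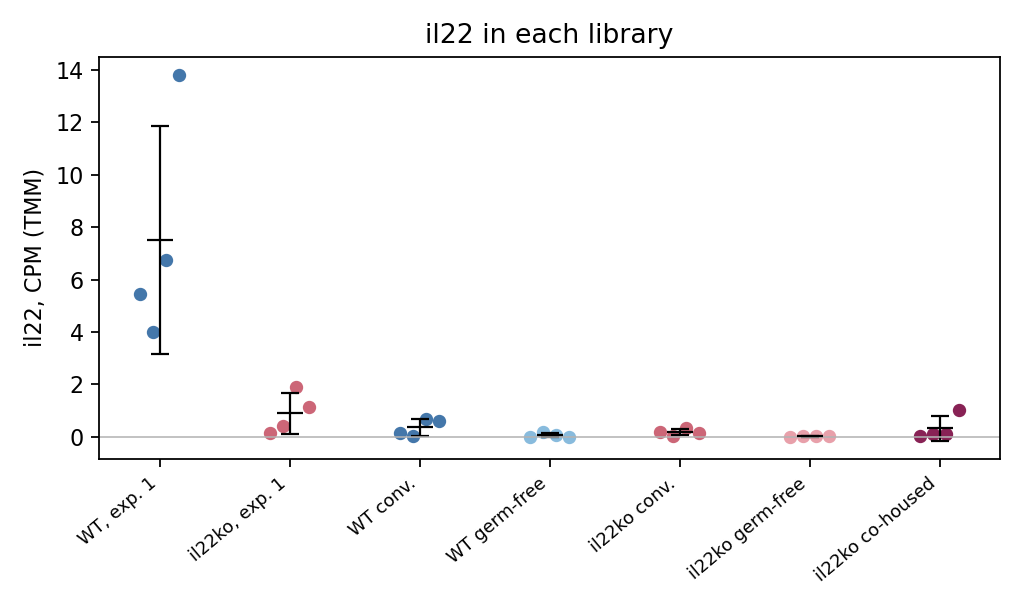
Expression of il22 in CPM (TMM-scaled) for the 28 libraries, with 1 point per library and the mean ± SD of each group of 4 as a bar. Wild type libraries of experiment 1 lay between 3.99 and 13.8 CPM, and no library of experiment 2 exceeded 1.03 CPM.

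The comparison of knockout with wild type in experiment 1 asked what loss of il22 changed in the gut. stat3, the transcription factor downstream of the receptor, fell from 213 ± 19.8 to 64.4 ± 14.5 CPM (SD, n = 4; log2 fold change −1.73 ± 0.15, adjusted p = 6.1e-05), and socs3b, a feedback inhibitor that STAT3 induces, fell from 137 ± 31.4 to 34 ± 9.76 CPM (adjusted p = 0.00033). Of 17 measured members of the IL-22 receptor and STAT3 list, 9 fell, 2 rose and 6 did not pass, and 11 fell when adjusted over the list alone. The soluble receptor gene il22ra2 fell by 1.51 and il6st, another member of the list, by 0.67 on the log2 scale. Camera called this list lower with an adjusted p of 0.00345, and the adjusted p = 0.975 with an estimated correlation.

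In the same comparison 16 of 29 immediate early and heat shock genes fell and 1 rose, with 20 lower when adjusted over the list alone. Both junba and junbb, which also belong to the STAT3 list, are among those that fell and are counted in each list. The inducible chaperone genes hsp70.2 and hsp90aa1.2 fell by 1.91 ± 0.31 and 1.14 ± 0.22 on the log2 scale, and hsp70l fell from 4.32 ± 0.678 to 0.760 ± 0.305 CPM (n = 4; adjusted p = 0.00018). The list had a camera adjusted p of 0.000518, and an adjusted p = 0.975 with an estimated correlation. Of single secretory genes, clca1, a gene of mucus-secreting epithelium, fell from 207 ± 12.2 to 12.9 ± 3.53 CPM (n = 4; adjusted p = 1.3e-06), the transmembrane mucin gene muc13b fell by 1.21 ± 0.08 and agr2, needed for mucin folding, by 0.86 ± 0.10 on the log2 scale; of 11 goblet and secretory genes 4 fell and 7 did not pass, with the same count when adjusted over the list alone, a median of 0.12 and a mean of −0.18, and the list was not called by camera (adjusted p = 0.304). Among 10 antimicrobial genes, of which 2 fell, the lectin gene itln2 had a log2 fold change of −7.21 ± 0.63. Outside the lists, noxo1b, an organizer of an epithelial NADPH oxidase, had one of −3.95 ± 0.68.

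Among genes higher in the knockout of experiment 1, uroc1, an enzyme of histidine breakdown, rose from 6.55 ± 0.951 to 171 ± 17.7 CPM (n = 4; adjusted p = 5.8e-08) and the epithelial keratin gene krt4 from 1007 ± 104 to 5601 ± 213 CPM (adjusted p = 2.7e-07). krt4 belongs to a list of skin epithelium genes, of which 6 of 22 rose and 2 fell (camera adjusted p = 0.00938, and adjusted p = 0.975 with an estimated correlation). Lysosome-rich enterocytes take up and digest luminal protein, and of 21 of their genes 12 rose and 4 fell, the same counts as when adjusted over the list alone. The protease genes lgmn and ctsz rose by 1.96 ± 0.20 and 1.58 ± 0.13, whereas ctsla had a log2 fold change of −1.03 ± 0.12. The camera adjusted p was 0.0396, with an adjusted p = 0.975 with an estimated correlation. Genes of lipid absorption (7 of 25 higher, 1 lower) included the fatty acid binding protein gene fabp1b.1 at 1.31 ± 0.19 and mogat2, which rebuilds triglyceride, at 1.19 ± 0.15. Of 11 bile acid genes 5 rose and 2 fell, including the bile acid receptor gene nr1h4 at 0.85 ± 0.09. Of 25 proliferation genes 9 fell and 16 did not pass, among them the replication helicase gene mcm4 at −0.60 ± 0.14; the camera adjusted p was 0.0489, with an adjusted p = 0.975 with an estimated correlation. Of 25 enteroendocrine genes 2 rose and 4 fell, including the irritant channel gene trpa1b at −0.69 ± 0.11, with a median of −0.12 and a mean of 0.13.

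In all, 3541 of 10710 genes tested changed between the genotypes of experiment 1, 1725 higher and 1816 lower in the knockout, with 451 and 442 past 2-fold. The libraries of the 2 genotypes did not overlap for 34.3% of genes, where chance gives 2.86%. Several of the largest differences were close to all or none. ggact.2, which belongs to a family of close copies and is uncertain for that reason, stood at 33.3 ± 1.16 CPM in the knockout and had no count in wild type, so that it was at least 1580-fold higher. rrm2l, at 6.97 ± 1.5 CPM in wild type, had no count in the knockout and was at least 293-fold lower.

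Conventional larvae of experiment 2 gave a separate measurement of the knockout effect. cldn15la, a claudin of intestinal epithelium, rose from 393 ± 28.7 to 1537 ± 187 CPM (SD, n = 4; adjusted p = 1.4e-07), and the scaffold gene tjp2a rose by 0.52 ± 0.07 on the log2 scale. Of 22 tight junction and adhesion genes 10 rose and 12 did not pass, the same when adjusted over the list alone. The list did not pass with camera (adjusted p = 0.0536). hmgcra, the rate-limiting enzyme of cholesterol synthesis, rose from 4.53 ± 1.75 to 33.1 ± 16.1 CPM (adjusted p = 0.00029), and 7 of 22 genes of that pathway were higher and 2 lower. Of 22 lysosome-rich enterocyte genes 12 rose and 2 fell, including ctsz at 1.01 ± 0.13 and dab2 at 0.73 ± 0.12 (camera adjusted p = 0.0675). krt4 rose by 2.13 ± 0.11.

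On the lower side, 9 of 25 lipid absorption genes fell and 2 rose, among them the apolipoprotein genes apoea at −0.87 ± 0.12 and apoa1a at −0.73 ± 0.10, while fabp1b.1 rose by 1.17 ± 0.14. Of 30 enteroendocrine genes 6 fell and 1 rose (5 lower and none higher when adjusted over the list alone), including tph1b, which makes serotonin, at −2.00 ± 0.43 and the calcitonin gene calca at −2.69 ± 0.52. Of 16 macrophage genes 7 fell and 3 rose, with mfap4.1 at −2.66 ± 0.30, and 7 of 14 erythrocyte genes fell. The elastase gene cela1.3, 1 of several close copies, fell from 190.5 ± 77.4 to 2.63 ± 0.988 CPM (adjusted p = 1.5e-08). Counted over all genes, 4070 of 11254 changed, 1918 higher and 2152 lower, and the libraries did not overlap for 31.3% of genes against 2.86% by chance. selenol stood at 50.2 ± 6.39 CPM in the knockout and 0.355 ± 0.116 CPM in wild type, and ggact.2 was at least 1260-fold higher. Here stat3 had a log2 fold change of 0.03 ± 0.15 (adjusted p = 0.908) and socs3b of 0.28 ± 0.16 (adjusted p = 0.188).

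The genotypes also differed without microbes. In germ-free larvae top2a, a topoisomerase of replicating cells, fell in the knockout from 11 ± 2.35 to 2.98 ± 0.467 CPM (SD, n = 4; adjusted p = 0.0002), and the mitotic genes kif11 and ccna2 fell by 1.47 ± 0.26 and 1.5 ± 0.33 on the log2 scale. Of 27 proliferation genes 9 fell and 18 did not pass, with 11 lower when adjusted over the list alone; the camera adjusted p was 0.0194, with an adjusted p = 1.00 with an estimated correlation. Of 16 macrophage genes 7 fell and 9 did not pass (8 fell when adjusted over the list alone), including spi1b, a master regulator of myeloid cells, at −1.17 ± 0.17 and havcr1 at −1.28 ± 0.26 (camera adjusted p = 0.0104, and adjusted p = 1.00 with an estimated correlation). Of 14 lymphocyte genes 5 fell and 1 rose, among them the cytokine receptor gene il2rga at −1.35 ± 0.23 and runx3 at −1.04 ± 0.17, but the list was not called by camera (adjusted p = 0.128). Of 12 neutrophil genes 3 rose and 2 fell, with the NADPH oxidase subunit gene ncf1 at 1.35 ± 0.19 and the receptor gene csf3r at −1.02 ± 0.23 (camera adjusted p = 0.923). Of 22 lysosome-rich enterocyte genes 12 rose and 3 fell, including ctsz at 0.97 ± 0.13 (camera adjusted p = 0.0456, and adjusted p = 1.00 with an estimated correlation). cldn15la rose by 1.44 ± 0.17, hmgcra by 4.32 ± 0.54 and krt4 by 1.94 ± 0.11. A total of 3020 of 11254 genes changed, 1521 higher and 1499 lower; on the TPM scale with a pseudocount of 1 the split was 1916 higher and 942 lower. The libraries did not overlap for 29.8% of genes, against 2.86% by chance.

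The knockout effects were compared between the settings. Of 1862 genes called in both experiment 1 and the conventional larvae of experiment 2, 889 were higher in both, 869 lower in both and 104 opposite, where independent lists would give 288.1, 333.2 and 620. Conventional and germ-free larvae shared no libraries, and of 2110 genes called in both, 1094 were higher, 1002 lower and 14 opposite. Over the genes called in conventional larvae, the germ-free effect had a slope of 0.847 on the conventional effect, to which genes of large effect contribute most. The median ratio of the germ-free to the conventional effect over these genes was 0.675. Because these genes were chosen by their conventional effect, a ratio under 1 could arise from that choice alone. The genes higher in the knockout of experiment 1, taken as a set, were also higher in the conventional knockout of experiment 2 (camera p = 3.5e-35 and p = 3.1e-05 with an estimated correlation), and the lower set was lower (camera p = 3.1e-21 and p = 2e-06 with an estimated correlation). krt4, ctsz and fabp1b.1 were higher in all 3 comparisons.

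Germ-free rearing was compared with conventional rearing within each genotype to ask what the microbiota changes. In wild type, several genes of the daily clock changed. nfil3-6, a rhythmically expressed repressor, fell from 99.6 ± 29.3 to 14.8 ± 2.87 CPM (SD, n = 4; adjusted p = 5.2e-06), and nr1d1, a core repressor of the clock, from 25.2 to 5.48 CPM (log2 fold change −2.2 ± 0.40, adjusted p = 0.00137). cry5, a photolyase-family gene driven by light, fell by 1.74 ± 0.14, while the activator gene clocka rose by 0.80 ± 0.15. Of 29 clock genes 12 fell and 3 rose, and 13 fell and 8 rose when adjusted over the list alone; the camera adjusted p was 0.00222, with an adjusted p = 0.93 with an estimated correlation. Of 24 interferon-responsive genes 13 rose in germ-free wild type and 11 did not pass (17 rose when adjusted over the list alone). stat1b, a transducer of interferon signals, rose from 1.47 ± 1.90 to 23.9 ± 18.7 CPM (adjusted p = 0.005), and stat2 by 1.39 ± 0.30. The camera adjusted p was 8.47e-06, with an adjusted p = 0.93 with an estimated correlation, and conventional wild type 4 stood apart with 4.30 CPM of stat1b against 0.357 to 0.786 CPM in the other 3.

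Of 26 genes of xenobiotic handling 10 fell in germ-free wild type and 16 did not pass, among them the efflux transporter genes abcg2a at −1.0 ± 0.11 and abcb4 at −0.55 ± 0.11 (camera adjusted p = 0.000802, and adjusted p = 0.147 with an estimated correlation). Of 22 lysosome-rich enterocyte genes 10 fell and 1 rose (15 and 1 when adjusted over the list alone), with plac8.1 at −1.14 ± 0.19 (camera adjusted p = 0.000802, and adjusted p = 0.93 with an estimated correlation). Of 25 lipid absorption genes 8 fell and 17 did not pass, with mttp, which loads lipid onto lipoproteins, at −0.52 ± 0.12 (camera adjusted p = 0.0192, and adjusted p = 0.93 with an estimated correlation). crtac1a, which encodes a secreted matrix protein, fell from 130.0 ± 8.24 to 7.65 ± 2.47 CPM (adjusted p = 1.1e-10). Of 32 pancreatic enzyme genes 7 rose and 25 did not pass, and cel.1 rose by 1.26 ± 0.33, with a camera adjusted p of 4.01e-05 and an adjusted p = 0.93 with an estimated correlation. Of 26 liver genes 2 fell (camera adjusted p = 0.00035, and adjusted p = 0.93 with an estimated correlation), and liver scores were 2.65 to 3.82 in the conventional and −0.223 to 2.54 in the germ-free libraries. Of 31 genes of fatty acid oxidation and fasting 12 fell and 2 rose, with angptl4 at 2.02 ± 0.46 (camera adjusted p = 0.0192, and adjusted p = 0.93 with an estimated correlation). In total 2838 of 11254 genes changed, 1357 higher and 1481 lower, and on the TPM scale with a pseudocount of 1 the split was 671 and 1937. The libraries did not overlap for 17.1% of genes, against 2.86% by chance. The count fell to 1695 without conventional wild type 3, to 1270 when the compared groups were fitted alone, to 1789 with a covariate for pancreas and liver transcripts, and to 1814 without the 3 libraries with muscle transcripts.

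The same comparison of rearing was made in the knockout. angptl4, a lipase inhibitor known to be kept low by gut microbes, rose from 24.5 ± 7.10 to 330.3 ± 81.9 CPM (SD, n = 4; adjusted p = 8.6e-05). cyp1a, the classic target of the aryl hydrocarbon receptor, fell from 613 ± 184 to 86.8 ± 20.1 CPM (adjusted p = 1.5e-05), and the receptor's repressor gene ahrra fell by 5.09 ± 0.71. Of 26 genes of this receptor and of xenobiotic metabolism 10 fell and 1 rose, with a camera adjusted p of 0.000689 and an adjusted p = 0.0771 with an estimated correlation. fkbp5, induced by glucocorticoids, fell from 642 ± 127 to 46.0 ± 24.4 CPM (adjusted p = 0.00089). Of 29 clock genes 10 fell and 10 rose, including nr1d1 at −3.24 ± 0.41, nfil3-6 at −2.93 ± 0.26 and clocka at 0.94 ± 0.15. Of 31 immediate early and heat shock genes 12 fell and 2 rose (18 and 2 when adjusted over the list alone), with nr4a1 at −4.29 ± 0.92; the camera adjusted p was 0.00284, with an adjusted p = 0.958 with an estimated correlation. Lysosome-rich enterocyte genes fell in 8 of 22 cases and rose in 1 (camera adjusted p = 0.000996, and adjusted p = 0.958 with an estimated correlation), and 4 of 16 macrophage genes fell (camera adjusted p = 0.0237, and adjusted p = 0.958 with an estimated correlation). Of 27 proliferation genes 11 fell and 16 did not pass (camera adjusted p = 0.00284, and adjusted p = 0.958 with an estimated correlation), among them mcm5 at −1.12 ± 0.33, a call that ended without germ-free knockout 1 and when the compared groups were fitted alone.

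A total of 3066 genes changed with germ-free rearing in the knockout, 1573 higher and 1493 lower, and the libraries did not overlap for 33.5% of genes, against 2.86% by chance. Of 1461 genes called in both genotypes, 721 were higher in both, 718 lower in both and 22 opposite, where independent lists would give 189.7, 196.5 and 387. Across genes, which are not independent replicates, the 2 effects had a Pearson correlation of 0.522.

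**Figure D2:**
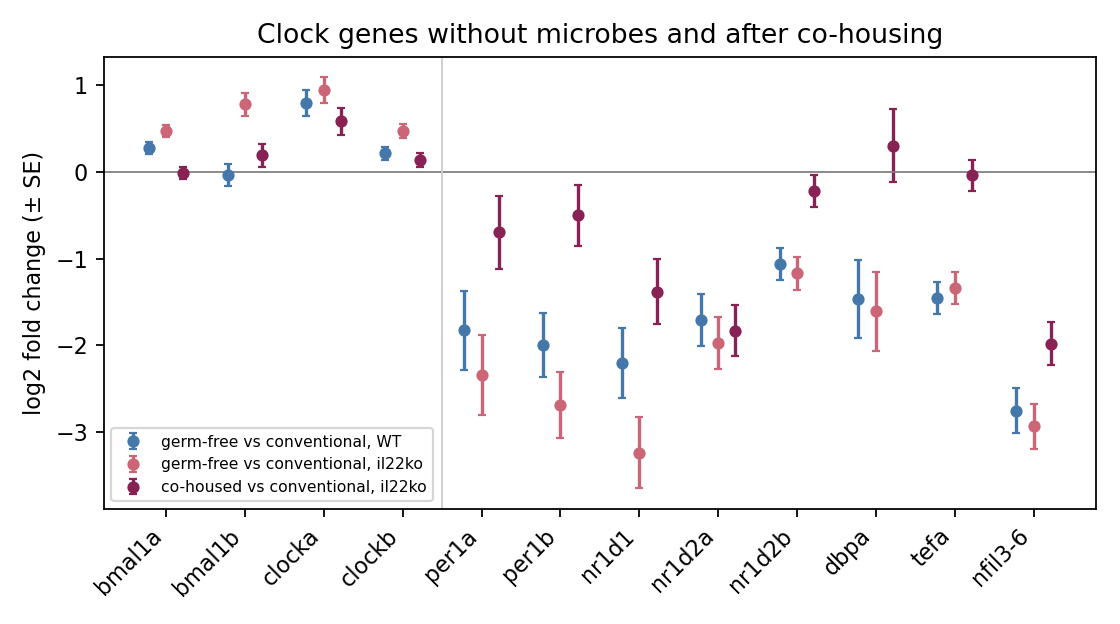
Log2 fold changes ± SE of 12 clock genes for germ-free against conventional wild type, germ-free against conventional knockout, and co-housed against conventional knockout (4 libraries per group, 1 point per gene and comparison). In germ-free wild type and knockout, nr1d1 fell by 2.2 and 3.24 and clocka rose by 0.80 and 0.94.

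Co-housed knockout larvae were compared with conventional knockout larvae to ask what co-housing changes in the gut. What they were housed with, and for how long, is not given in the sources used here. Against the conventional knockout, nfil3-6 fell from 215 ± 30.5 to 54.3 ± 18.7 CPM (SD, n = 4; adjusted p = 0.00065) and klf9, a transcription factor induced by glucocorticoids, from 325 ± 49.1 to 131 ± 42.3 CPM (adjusted p = 0.0058). cyp1a fell from 613 ± 184 to 228 ± 67.7 CPM (adjusted p = 0.013), and angptl4 rose from 24.5 ± 7.10 to 141 ± 109 CPM (adjusted p = 0.01); both calls ended when the compared groups were fitted alone. The growth regulator gene mycn rose by 1.1 ± 0.13, and the NF-κB inhibitor genes nfkbiaa and nfkbiab fell by 1.02 ± 0.19 and 0.88 ± 0.15. Of 16 STAT3 list genes 2 fell and 14 did not pass (5 lower when adjusted over the list alone), with cebpd at −1.24 ± 0.17 (camera adjusted p = 0.000168, and adjusted p = 0.941 with an estimated correlation). Of 29 clock genes 2 rose and 2 fell, nfil3-6 and nr1d2a, the latter by 1.83 ± 0.30. Pancreatic enzyme genes were called higher by camera (adjusted p = 2.69e-08, and adjusted p = 0.941 with an estimated correlation), although 1 of 32 rose and 31 did not pass. Tight junction genes were called lower (adjusted p = 0.0289, and adjusted p = 0.941 with an estimated correlation) with 1 of 22 lower, a median of −0.11 and a mean of 0.14.

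The co-housing effect was small in number: 292 of 11254 genes changed, 169 higher and 123 lower, with 1961 genes at an unadjusted p under 0.05 and 614 called by DESeq2. On the TPM scale with a pseudocount of 1 the count was 176, with 58 higher and 118 lower. It depended on single libraries, being 179, 115, 174 and 150 without conventional knockout 1 to 4 and 182, 495, 114 and 102 without co-housed knockout 1 to 4, and it was 564 without the 3 libraries with muscle transcripts. The libraries did not overlap for 12.6% of genes, against 2.86% by chance. Genes called for both genotype and co-housing were opposite in 148 cases, higher in both in 8 and lower in both in 10, where independent lists would give 53.3, 28.8 and 23.5. Both comparisons use the conventional knockout, which alone gives a negative correlation and covariance. Across genes the correlation was −0.295, against −0.5 on average in simulations with no effect (−0.558 to −0.456 over 20 simulations), and the covariance was −0.135, against −0.0499 in the same simulations. With the shared libraries split 2 and 2 between the comparisons, which leaves each fewer libraries, the correlation averaged −0.208 and the covariance −0.129, and 4 to 20 genes were called in opposite directions over 6 splits and 0 to 6 in the same direction.

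**Figure D3:**
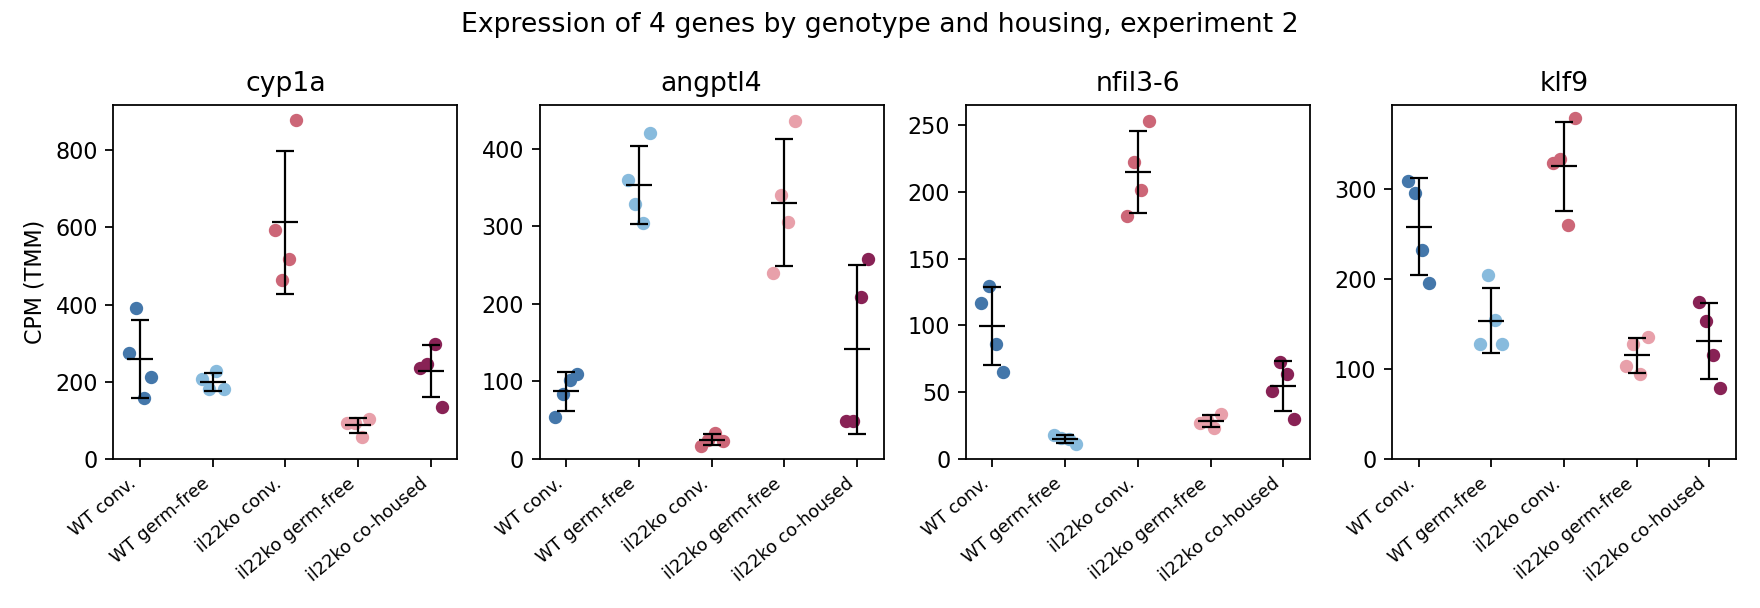
Expression of cyp1a, angptl4, nfil3-6 and klf9 in CPM (TMM-scaled) in the 5 groups of experiment 2, with 1 point per library and the mean ± SD of 4 libraries as a bar. In the knockout, co-housed means of 228, 141, 54.3 and 131 CPM lay between the conventional means of 613, 24.5, 215 and 325 CPM and the germ-free means for cyp1a, angptl4, nfil3-6 and klf9.

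Co-housed knockout was also set against conventional wild type, to ask which genotype differences were still present after co-housing. Of 11254 genes 3733 changed, 1810 higher and 1923 lower. With the germ-free comparison of genotypes, which shares no libraries with it, 1098 genes were higher in both, 1002 lower in both and 11 opposite, where independent lists would give 244.6, 256.1 and 501. The libraries did not overlap for 26% of genes, against 2.86% by chance. cldn15la stayed higher by 1.42 ± 0.17, hmgcra by 3.65 ± 0.51 and krt4 by 1.88 ± 0.10 on the log2 scale. abcg2a, the efflux transporter, fell from 4413 ± 514 to 2662 ± 257 CPM (SD, n = 4; adjusted p = 4.8e-05). Of 32 pancreatic enzyme genes 11 rose and 1 fell, including cel.2 at 1.99 ± 0.34 and cpa4 at 1.80 ± 0.32, with a camera adjusted p of 0.0409 and an adjusted p = 0.98 with an estimated correlation. Of 26 liver genes 8 fell and 18 did not pass, among them the retinol carrier gene rbp4 at −0.93 ± 0.13, in a comparison whose wild type libraries had liver scores of 2.65 to 3.82 and whose co-housed libraries had −0.237 to 1.96 (camera adjusted p = 0.0409, and adjusted p = 0.98 with an estimated correlation). With a covariate for pancreas and liver transcripts the liver list turned direction (adjusted p = 0.77). The count of changed genes was 2465 both with that covariate and with the compared groups fitted alone.

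Whether the knockout effect differed between conventional and germ-free larvae was tested as an interaction. Of 11254 genes 50 passed, 13 with a more positive and 37 with a more negative effect in conventional larvae, and 1679 had an unadjusted p under 0.05. For cyp1a the knockout effect was 1.24 ± 0.28 in conventional and −1.20 ± 0.28 in germ-free larvae on the log2 scale, a difference of 2.44 ± 0.40 (adjusted p = 0.017) that was not called without the 3 libraries with muscle transcripts. cyp2aa12, a cytochrome P450 gene, differed by 0.94 ± 0.13 (adjusted p = 0.0067). In the other direction, crtac1a differed by −1.87 ± 0.24 (adjusted p = 0.0026) and the clock repressor gene cry3b by −0.80 ± 0.13 (adjusted p = 0.013). Camera called 27 proliferation genes more positive in conventional larvae (adjusted p = 2.89e-06, and adjusted p = 0.742 with an estimated correlation), with no member past the gene test and a median difference of 0.74, and 29 clock genes more negative (adjusted p = 0.00482, and adjusted p = 0.742 with an estimated correlation), with 2 past it. On the TPM scale with a pseudocount of 1, 7 genes were higher and 45 lower, and DESeq2 called 366. The count was 989 without conventional wild type 4 and 29, 29 and 21 without conventional wild type 1 to 3, 32 and 17 without germ-free wild type 1 and 2, 31 and 7 without conventional knockout 1 and 2, and 29, 32 and 21 without germ-free knockout 1, 3 and 4.

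The knockout effect of experiment 1 was tested against that of conventional larvae in experiment 2 to ask where the experiments differed. Of 17 STAT3 list genes 6 had a more negative effect in experiment 1 and 11 did not pass, and 7 had it when adjusted over the list alone. stat3 differed by −1.76 ± 0.23 (adjusted p = 0.00022) and socs3b by −2.30 ± 0.30 (adjusted p = 0.00024). The camera adjusted p was 2.19e-07, with an adjusted p = 0.439 with an estimated correlation. Of 31 immediate early and heat shock genes 11 differed in the same direction (17 when adjusted over the list alone), among them hsp70.2 by −2.51 ± 0.57, with a camera adjusted p of 8.86e-10 and an adjusted p = 0.358 with an estimated correlation. junba and junbb belong to this list and to the STAT3 list and are counted in each, so the lists are not separate evidence. Of 20 tight junction genes 7 differed in that direction, among them cldn15la at −1.86 ± 0.13, with a camera adjusted p of 6.79e-06 and an adjusted p = 0.358 with an estimated correlation. The replication genes mcm5 and mcm6 differed by −1.47 ± 0.20 and −1.59 ± 0.25, among 7 of 26 proliferation genes (camera adjusted p = 1.33e-05, and adjusted p = 0.638 with an estimated correlation). Of 25 lipid absorption genes 6 had a more positive effect in experiment 1 and 19 did not pass, with mogat2 at 0.99 ± 0.20 (camera adjusted p = 0.000113, and adjusted p = 0.638 with an estimated correlation). cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 2.79 ± 0.55. Skeletal muscle genes differed in 4 of 24 cases (camera adjusted p = 0.000635, and adjusted p = 0.687 with an estimated correlation), in a comparison that holds the conventional wild type library of muscle score 5.40. clca1 differed by −3.66 ± 0.32. In all 1096 of 11047 genes differed, 536 more positive and 560 more negative in experiment 1, and on the TPM scale with a pseudocount of 1 the split was 366 and 712. The count was 1900 without conventional wild type 4 and 659 with a covariate for pancreas and liver transcripts.

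**Figure D4:**
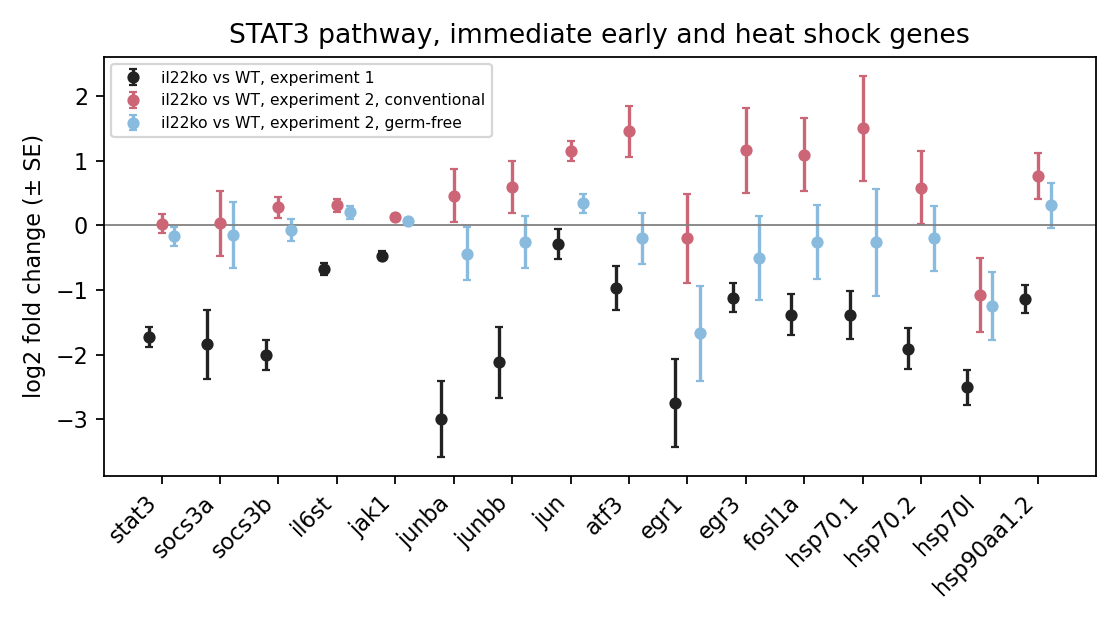
Log2 fold changes ± SE of knockout against wild type for 16 genes of the STAT3 pathway, the immediate early response and heat shock, in experiment 1 and in conventional and germ-free larvae of experiment 2 (4 libraries per group, 1 point per gene and comparison). stat3 stood at −1.73 in experiment 1 and at 0.03 in conventional larvae, and socs3b at −2.01 and 0.28.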

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

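The tests of the haplotype around il22, of different microbes in the lines, of the time of day and of the lower depth in experiment 2 were chosen only after the results they bear on were seen, as was the removal of the libraries with muscle transcripts.

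The first pattern is the genotype difference that recurred in both experiments and without microbes. A haplotype carried along with the il22 allele could place changed genes near it. Within 10 Mb of il22 lay 2.5% of the called genes of experiment 1, a share that decides nothing. The window held only 234 tested genes against 3474 called, so the share was bound to be low. Of genes in the window 37.2% were called against 33% of the others (odds ratio 1.203, Fisher's exact p = 0.182, two-sided). On the whole chromosome 37.3% were called against 32.9% (odds ratio 1.217, Fisher's exact p = 0.0624). Called genes were thus not clearly crowded near il22, which leaves effects of the haplotype on distant genes undecided. Different microbes in the lines, as the whole cause, would leave little effect in germ-free larvae. Over the genes called in conventional larvae, the germ-free effect had a slope of at least 0.78 on the conventional effect without any 1 library. This slope gives most weight to genes of large effect. With all libraries, the median ratio of the germ-free to the conventional effect over these genes was 0.675, and 91.5% had the same sign. Choosing genes by their conventional effect can by itself lower this ratio, so it does not size a part played by microbes. These values argue against microbes as the whole cause, while a part played by them stays open. Lower depth of the knockout does not account for the count, since 3996 genes changed with every library thinned to the smallest total, against 4070. Effects of the haplotype on distant genes, other differences between the lines across the genome, and loss of il22 itself were not tested. They stay open.

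The second pattern is the germ-free effect on clock genes. Without conventional wild type 1 and germ-free wild type 2, 11 of the 15 clock genes called in wild type were called in the same direction, which argues against muscle transcripts as the whole cause. The activator genes bmal1a, bmal1b, clocka and clockb averaged 0.31 ± 0.35 (SD, n = 4 genes) and 7 output and repressor genes −1.67 ± 0.38 (SD over genes) in wild type, a gap of 1.99 on the log2 scale, and the gap was 2.71 in the knockout, 0.849 for co-housing, and −0.755 and −0.757 between the genotypes of experiment 1 and of conventional larvae. In wild type the gap came mostly from the output arm. There bmal1a at 0.271 and clocka at 0.795 passed the threshold, and bmal1b at −0.034 and clockb at 0.211 did not. In the knockout bmal1a, bmal1b, clocka and clockb rose by 0.473, 0.778, 0.939 and 0.467, all past the threshold. Opposite movement of the arms, clearer in the knockout, could come from groups collected at different phases of the day. Such phases could also differ between groups with no germ-free member. This explanation stays open together with an effect of the microbes on the clock, since the labels used here give no collection time.

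The third pattern is that STAT3 and immediate early genes were lower in the knockout of experiment 1, with a different effect in experiment 2. Depth does not account for it: with the libraries of experiment 1 thinned to the smallest total of experiment 2, 21 of the 23 list members lower in experiment 1 were called lower. Stress from handling could move both lists, and over the 20 libraries of experiment 2 deviations of the stress and STAT3 scores from their group means had a Pearson correlation of 0.521 (permutation p = 0.0613) and a Spearman correlation of 0.55 (permutation p = 0.0256), with Pearson 0.468 without the 2 libraries farthest from the median. Handling stress and the biological explanation, loss of a cytokine that averaged 7.50 CPM in wild type of experiment 1 and reached at most 0.68 CPM in any wild type library of experiment 2, cannot be told apart, because the scores moved together in experiment 2 without passing both tests and housing in experiment 1 is not stated.

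The genotype and treatment counts were set against other splits of the same libraries, 35 for each pair of groups and 100 drawn for the comparisons of effects. For each pair of groups, 1 of 35 splits, the real one, called as many genes. For the knockout the counts were 3541 in experiment 1 (highest other split 1), 4070 in conventional larvae (highest other 1018) and 3020 in germ-free larvae (highest other 12). For germ-free rearing they were 2838 in wild type (highest other 2429) and 3066 in the knockout (highest other 0). Co-housing gave 292 (highest other 1), and the co-housed knockout against wild type gave 3733 (highest other 2128). A share of 1 of 35 is the smallest that these splits allow, and it was not adjusted over the comparisons. The splits alone therefore do not exclude chance. The highest other splits of the 3 comparisons with conventional wild type set its libraries 1 to 3 apart from library 4, which points to a structure of the samples. For the difference between conventional and germ-free knockout effects 4 of 100 splits gave as many genes (50, highest other 3051), and for the difference between experiments 3 of 100 did (1096, highest other 2621). Their shares lie under 5%, but these splits do not hold the genotype effect fixed. The highest ones kept 1 genotype contrast whole and mixed the other, which carries the genotype effect itself into the difference. The shares therefore cannot decide whether chance could give these counts.

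Among 97 groups of 4 libraries tested for a library far from the others, 5 had one, and chance gives about 5%. Conventional wild type 4 had a liver score of 3.82 (others 2.65 to 2.85) and 4.30 CPM of stat1b (others 0.357 to 0.786). Germ-free knockout 3 had a muscle score of 2.13 (others 0.348 to 0.43). For il22, co-housed knockout 4 stood at 1.03 CPM (others 0.048 to 0.128) and germ-free knockout 1 at 0 CPM (others 0.039 to 0.04). The germ-free knockout libraries held 0 to 1 count of il22, so their difference lies at the limit of detection.

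The knockout effect differed between conventional and germ-free larvae for 50 genes, a count that lay between 7 without conventional knockout 2 and 989 without conventional wild type 4. Differences in log2 fold change were 2.44 for cyp1a, 0.99 for gpr160, 0.94 for cyp2aa12, 0.93 for fam114a1 and 0.86 for rnf19b, and −3.31 for fthl28, −2.43 for cyp26a1, −2.43 for atp1a1a.3, −1.87 for crtac1a, −1.87 for cyp8b1.1, −1.07 for cry5, −0.88 for rbp4 and −0.80 for cry3b. The calls of crtac1a, cyp2aa12 and cry3b held under every alternative and without each library. That of fthl28 ended without conventional knockout 2, that of cyp26a1 without germ-free wild type 2 or conventional knockout 2, and that of cry5 without conventional wild type 3, germ-free wild type 2, conventional knockout 2 or germ-free knockout 4. Those of gpr160, fam114a1, rnf19b, atp1a1a.3, cyp8b1.1 and rbp4 each ended without any of at least 7 single libraries.

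The knockout effect differed between the experiments for 1096 genes. Among the genes of largest difference, log2 values were −3.66 for clca1, −6.18 for plac8.2, −4.31 for noxo1b, −5.23 for tsc1a, −8.33 for mhc2dhb, 9.24 for hsd11b1la, 6.91 for hmg20b, 6.34 for hnrnpdl, 4.71 for cela1.3 and 4.41 for vtg3. mhc2dhb had no count in the knockout of experiment 1, at least 167-fold below wild type, and hmg20b none in its wild type, so their fitted values are no bounds. In experiment 1 hmg20b averaged 0.643 CPM in the knockout, and tsc1a 0.0762 CPM in the knockout and 0.0642 CPM in wild type. For both genes the minimum of 5 CPM was met only in a group of experiment 2. Genes of the fixed lists differed by −1.76 for stat3, −2.30 for socs3b, −3.48 for junba, −2.73 for junbb, −0.61 for jak1, −0.99 for il6st, −1.46 for jun, −2.44 for atf3 and −2.51 for hsp70.2, by −1.47 for mcm5 and −1.59 for mcm6, by −1.86 for cldn15la and −1.98 for cldnb, and by 2.79 for cyp7a1, −2.81 for ahrra and 0.99 for mogat2. The calls of junba, junbb, jun, atf3, cldnb, ahrra and noxo1b ended with the covariate for pancreas and liver transcripts. Those of hmg20b, hnrnpdl and mhc2dhb ended on the TPM scale, that of tsc1a without wild type 2 of experiment 1, that of noxo1b without conventional knockout 1, and that of junbb without any of 8 single libraries.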

How the results depend on the processing

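Summing rows of a symbol, removing the libraries with muscle transcripts, thinning and the split of libraries shared by co-housing and germ-free rearing were chosen after seeing the data. Counts of changed genes moved by over 1.5 times in 5 comparisons, and the cause was not tested. For germ-free against conventional wild type (2838) they were 1789 with a covariate for pancreas and liver transcripts, 1270 with the compared groups alone, 1814 without the 3 libraries of highest muscle score, and 1695 (without conventional wild type 3) to 4154 (without library 4) when 1 library was left out. For co-housing (292) they were 614 with DESeq2, 176 and 171 on log2 of TPM plus 1 and plus 0.1, 564 without the muscle libraries and 102 (without co-housed knockout 4) to 495 (without library 2) with 1 left out. For the co-housed knockout against wild type (3733) they were 2465 both with the covariate and with the groups alone. For the interaction (50) they were 30 with the covariate, 366 with DESeq2, 25 on TPM plus 0.1, 82 with the groups alone, 13 without the muscle libraries, and 7 (without conventional knockout 2) to 989 (without conventional wild type 4). For the difference between experiments (1096) they were 659 with the covariate and 798 (without wild type 4 of experiment 1) to 1900 (without conventional wild type 4). The other counts stayed within 1.5 times.

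The genes higher in the knockout of experiment 1 were called lower with co-housing by camera (p = 0.00259), but not with an estimated correlation (p = 0.175) or by fry (p = 0.0926). With the covariate 2 list tests turned direction, those of liver genes in the co-housed knockout against wild type (adjusted p = 0.77) and of complement genes in the interaction (adjusted p = 0.825). The correlation of the conventional genotype effect with the germ-free effect in wild type, 0.146, was −0.052 with the shared libraries split, and that of the co-housing with the germ-free effect in the knockout, 0.677, was 0.426. Of 14531 calls of named genes across settings 13326 held, 1205 were lost and 0 reversed, and 757 of the losses came from leaving out 1 library. Of 3945 list tests 3669 kept their status, 204 calls were lost, 70 gained and 2 reversed. Lists that were not called and stayed so count as kept, so the share kept does not measure how well calls held. With the estimated correlation, 52 calls were lost, and the 218 tests that kept their status were all of lists not called. Of simulated 1.5-fold changes, edgeR recovered 40.3% and DESeq2 55.2% for the conventional comparison of genotypes, and 9% and 19.4% for the difference between experiments. The DESeq2 shares counted calls in either direction, and no share of unchanged genes among its calls was computed.

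With a replicate block the counts were 3349, 4006 and 2976 for the knockout in experiment 1, conventional and germ-free larvae, 2854 and 3046 for germ-free rearing in wild type and knockout, 242 and 3672 for the co-housed knockout against its conventional counterpart and wild type, 56 for the interaction and 817 between experiments. Libraries with the same number share only a number: 2 of 8 libraries in experiment 1 and 6 of 20 in experiment 2 correlated best with their own number, and correlations within a number ran from −0.084 to 0.289 and from −0.431 to 0.359.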

Other observations

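The test of sharing between co-housing and germ-free effects used a split of libraries chosen after seeing the data, and the genes that separate the lines were also looked for after the genotype effects were seen.

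Genes of gut muscle and bile acid handling, which the comparisons above did not describe in full, showed several changes. myl9b, a myosin light chain of smooth muscle, was higher in the knockout by 0.77 ± 0.15 in experiment 1, 1.15 ± 0.11 in conventional and 1.22 ± 0.11 in germ-free larvae on the log2 scale. Of 20 smooth muscle and interstitial cell genes 5 were higher and 1 lower in the conventional knockout, with the mesenchymal gene pdgfra at 0.55 ± 0.12, and the list was not called by camera (adjusted p = 0.263, with a median of 0.03 and a mean of −0.14). In germ-free wild type 5 of the 20 fell and 2 rose, among them the smooth muscle actin gene acta2 at −0.56 ± 0.12 (camera adjusted p = 0.214). Of 27 enteric neuron and glia genes 2 fell in the conventional knockout, ascl1a at −0.81 ± 0.23 and ddc at −0.76 ± 0.13. The bile acid receptor gene nr1h4 was higher in the knockout by 1.3 ± 0.11 in conventional and 1.06 ± 0.11 in germ-free larvae, and the ileal bile acid transporter gene slc10a2 was lower in germ-free guts, at −1.17 ± 0.27 in wild type and −1.04 ± 0.26 in the knockout.

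Among 9742 genes named in both tables with a mean of at least 1 CPM, each of the 16 knockout libraries lay above each of the 12 wild type libraries for 235, and below for 165. For 13 and 9 of them the gap was at least 4-fold. selenol ranged from 31.8 to 57.3 CPM in the knockout libraries and from 0.093 to 0.661 CPM in wild type, and acbd4 from 0.743 to 1.33 CPM and from 8.63 to 16.5 CPM. In 4 cases no wild type library had a count and each knockout library had 1 CPM or more, and in 2 the reverse held. These levels are set across 2 tables that were counted separately, so they describe the libraries and were not tested.

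A hypothesis from these data is that co-housing moved the knockout gut in the direction of germ-free rearing. Of 250 genes called in both comparisons of the knockout 151 were higher in both, 98 lower in both and 1 opposite, where independent lists would give 23.6, 16.3 and 39.6. Both comparisons use the conventional knockout libraries, so the correlation of 0.677 across genes was set against 0.496 simulated with no effect, and the covariance of 0.2037 against 0.0496, with 0.0635 the highest of 20 simulations. With the shared libraries split 2 and 2, which leaves each comparison fewer libraries, 9 to 56 genes over 6 splits were called in the same direction in both and 0 in opposite directions, against 249 and 1 unsplit. The correlation was then at least 0.295 and the covariance averaged 0.1724. Shared libraries alone are therefore unlikely to account for the similarity, while what the larvae were housed with is not given in the sources used here, and differences in microbial load, in collection time or in those particular conventional libraries remain open. A move of the co-housed knockout towards conventional wild type is open as well. Genes called for both genotype and co-housing were opposite in 148 cases and in the same direction in 18. The covariance of those effects was −0.135, against −0.0499 simulated with no effect, and averaged −0.129 with the shared libraries split.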
